A study of Oryza sativa with 4 samples.

How the data were processed

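Whole-genome bisulfite sequencing was used to read cytosine methylation in seedlings of 2 rice cultivars, Nipponbare (a japonica cultivar) and 93-11 (an indica cultivar). Bisulfite turns unmethylated cytosine into uracil and leaves methylated cytosine, so the share of reads that keep a C at a position is its methylation level. Per the labels, plants were grown in nutrient solution with 10 h of light and 14 h of dark at 800 μmol m-2 s-1 and were harvested at 3 weeks. DNA came from a plant column kit, libraries from a KAPA kit, and sequencing from an Illumina HiSeq instrument, per the labels' protocols. The protocol text also names a kit for removing ribosomal RNA, although the molecule is labelled genomic DNA. There were 4 samples, 2 labelled replicates for each cultivar. The labels do not say whether these were separate plants or cultures.

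For each cultivar there was 1 list of methylated cytosines, which the labels of both replicates name, so the values are the authors' combined values with no spread between replicates. Per the submitters' processing notes the reads were processed with Bismark; its version, the genome builds and the rule for calling a cytosine methylated are not given in the sources used here. Each deposited line gives a position, a strand, a context (CG, CHG or CHH, where H is A, C or T), the coverage as a count of reads, a count of methylated reads, and the methylation level as a fraction with 2 decimals. Unmethylated cytosines are not in these lists, so every level below is the level of listed cytosines and not of the genome. No cytosine in either list had a coverage under 10 or fewer than 2 methylated reads.

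How the deposited numbers were combined was checked on the values. The fraction matched the ratio of the 2 counts as given, within 0.005, at 48.1% of lines in Nipponbare and 48.5% in 93-11. It matched at 100% of lines in both lists when each count was taken as the mean of 2 libraries rounded up. With rounding down the shares were 73.6% and 72.5%. The coverage was therefore read as the mean of both replicates, and the level as the ratio of their summed reads. Levels over many cytosines were computed by weighting each deposited fraction by its coverage. Dividing the rounded counts was an alternative.

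The main analysis used chromosomes 1 to 12. It held 12471790 of 12579549 lines for Nipponbare and 12338510 of 12491092 for 93-11, and 0 lines failed to parse. Median coverage was 16 in both lists, with quartiles of 14 and 20 in Nipponbare and of 13 and 19 in 93-11. Intervals are 95% Wilson intervals on the summed reads and cover counting error only, because no replicate value was used. They may be too narrow even for that. Reads without molecular identifiers are not independent molecules, and 1 read can cover several cytosines. No test between cultivars was made. The minimum of 5 reads chosen before the data were examined removed no cytosine, since both lists start at 10.

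The lists use different assemblies with different coordinates. The table of genes at hand is for assembly ASM3414082v1, which was not shown to be the build of either list, so none of its coordinates were used. Methylation over genes, genes differing between the cultivars, the members of the gene lists and the number of sites per reference cytosine were therefore not analysed here. The rule fixed before the data were examined named the genes with the most extreme gene levels and the members of fixed lists, and it could not be applied.

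To compare the same sequence in both cultivars, listed CG dinucleotides were reduced to the distances between neighbours. A run of 8 consecutive distances found in only 1 place in each list was taken as a match, in the same or the opposite direction. A match was kept where at least 5 others lay within 50 kb and 20 kb of offset. Cytosines under matches of the same chromosome number and direction were then paired base by base, leaving out bases with more than 1 offset. The method was chosen after seeing the data, and both 6 and 8 distances were tried before 8 was chosen. Because matches require identical spacing of listed CG sites, they favour conserved and well covered sequence. Shuffling the distances of 93-11 within each chromosome, in 1 shuffle, left 0 collinear matches of either direction.

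CHG sites were called CCG where the adjacent CG was listed, and CAG or CTG where the CHG partner on the other strand was listed. Arrays were runs of at least 24 CHH sites on 1 strand in which at least 70% had a site 7 bp on, with at least 25 sites per 100 bp and no gap over 21 bp. Windows were 100 kb and bins 1 kb. These definitions were also chosen after seeing the data. The functions were tested on simulated data; the tests of site matching and of CHG classes were added after a first run on the lists and changed no value. With 60000 simulated CG dinucleotides of which 5% were lost in each list, 100% of the matches were at the true place. For 38930 simulated sites the share listed in both was 54.1% against 53.8% as made. Of 18675 simulated CHG sites, 100% were put in the right class. That simulation listed every CG and CHG cytosine, so it did not test lists in which neighbours are absent. In the lists 48.4% of CHG sites in Nipponbare and 47.0% in 93-11 were put in neither class. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

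Alternatives fixed before the data were examined were other coverage minimums, the mean level, the share of sites with a level of at least 50%, all sequences, a limit at the 99th percentile of coverage, and each strand alone. Alternatives added later were a minimum of 20 reads, ranges of coverage, rounded counts, equal coverage (the mean level at each coverage from 10 to 40 reads, averaged with the same weights in both lists), other match settings, other array sizes, other CHG classes and a moved chromosome block.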

Results

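Cytosine methylation was compared between seedlings of Nipponbare, a japonica rice, and 93-11, an indica rice. The study's title concerns adenine methylation in both genomes, and these bisulfite libraries read methylated cytosine beside it. Each cultivar had 2 labelled replicates, given as the authors' combined list of methylated cytosines. The lists held 12471790 cytosines on chromosomes 1 to 12 in Nipponbare and 12338510 in 93-11, at a mean coverage over all listed cytosines of 18.2 and 17.2 reads. There was no replicate spread to set differences against, so differences are given with counting error only.

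Methylated cytosines were most numerous in the CG context, followed by CHG and CHH, in both cultivars. Nipponbare had 6198811 listed CG sites, 3704519 CHG sites and 2568460 CHH sites, or 49.7%, 29.7% and 20.6% of its list. In 93-11 there were 6097780 CG, 3536095 CHG and 2704635 CHH sites, or 49.4%, 28.7% and 21.9%. Per kb of sequence up to the last listed site, Nipponbare had 16.6 CG, 9.92 CHG and 6.88 CHH sites, and 93-11 had 15.7, 9.12 and 6.98. A listed number depends on depth as well as on methylation, because cytosines under 10 reads are absent.

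The contexts differed in how fully a listed cytosine was methylated. Listed CG sites were nearly fully methylated, with a read-weighted level of 94.1% in Nipponbare (95% interval 94.056 to 94.062) and 93.6% in 93-11 (93.622 to 93.628). CHG sites had 72.6% (72.63 to 72.65) and 71.1% (71.06 to 71.07). CHH sites had 41.3% (41.25 to 41.27) and 42.6% (42.59 to 42.61). In Nipponbare 93.7% of CG sites, 51.0% of CHG sites and 8.44% of CHH sites had a level of at least 80%. The same shares in 93-11 were 93.0%, 48.6% and 9.91%. Levels under 30% were found at 41.3% of the CHH sites of Nipponbare and 39.4% of those of 93-11.

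**Figure D1:**
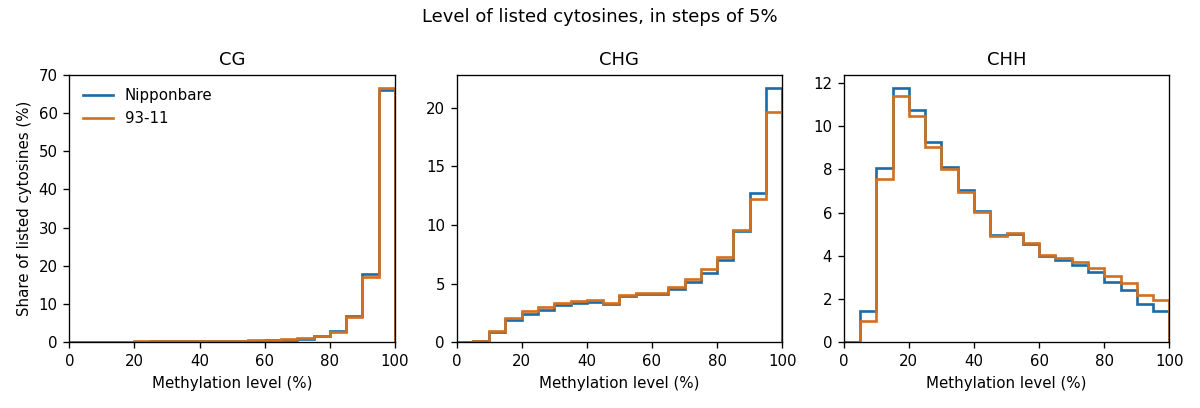
Share of listed cytosines (vertical axis, percent) by methylation level in steps of 5% (horizontal axis) in CG, CHG and CHH, with 1 line per cultivar. CG levels pile up at the top, with 66.0% of Nipponbare CG sites at 95% or more, while CHH levels peak under 30%.

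Listed CHG sites had a higher level in Nipponbare than in 93-11 and listed CHH sites a lower one. The CHG difference was 1.58 percentage points (1.57 to 1.59) and the CHH difference was -1.35 points (-1.36 to -1.33), as Nipponbare minus 93-11. The CG difference was 0.434 points (0.430 to 0.439). As a plain mean over cytosines the CG difference was 0.221 points, and as a mean at equal coverage, for sites of 10 to 40 reads, it was 0.0482 points. The CHG and CHH differences at equal coverage were 1.11 and -1.85 points. At sites of 10 to 14 reads the CG difference was -0.293 points, and at sites of 30 or more reads the CHG difference was -0.368 points.

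The same directions held on each chromosome. Nipponbare had the higher CG and CHG level on 12 of 12 chromosomes and the higher CHH level on 0. The CHG difference ran from 1.08 points on chromosome 1 to 2.29 on chromosome 10. The CHH difference ran from -2.23 points on chromosome 4 to -0.332 on chromosome 7. Chromosomes 2 and 7 do not hold the same sequence in both lists, and with a block of 93-11 chromosome 2 moved to chromosome 7, as described with the block, its CHH level on chromosome 7 went from 40.9% to 41.8%. Chromosome 11 had the lowest CHG and CHH levels in both cultivars, at 71.4% and 38.6% in Nipponbare and 69.2% and 39.3% in 93-11. It also had the largest ratio of CHG density, 1.17 times higher in Nipponbare. Chromosomes share libraries and are not replicates.

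**Figure D2:**
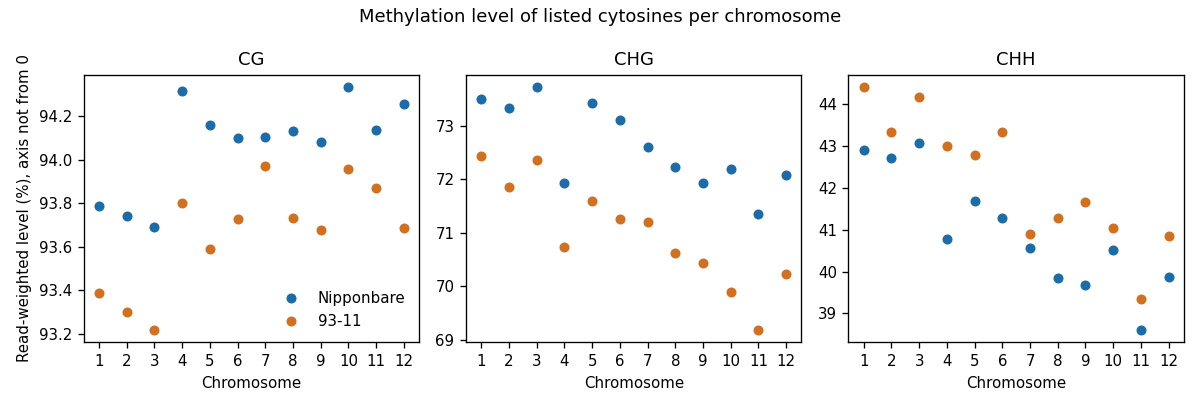
Read-weighted methylation level of listed cytosines (vertical axis, percent, not from 0) on chromosomes 1 to 12 (horizontal axis) in each context, 1 point per cultivar and chromosome. Nipponbare lies above 93-11 on 12 of 12 chromosomes for CG and CHG and on 0 for CHH.

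CG and CHG sites were concentrated in the same regions, and CHH sites were not. Across 3730 windows of 100 kb in Nipponbare, the numbers of CG and CHG sites correlated with r = 0.938 (rho = 0.941), and those of CG and CHH sites with r = -0.0860 (rho = -0.117). In 3870 windows of 93-11 the values were 0.913 (rho = 0.919) and -0.152 (rho = -0.194). Windows are not independent replicates. In the fifth of windows with the fewest CG sites, Nipponbare had 0.721 CHH sites per CG site, and in the fifth with the most it had 0.249. These ratios were 0.741 and 0.269 in 93-11. Most of this fall came from the CG number, by which the windows were sorted. Mean CG sites per window went from 943 to 2552 in Nipponbare and from 968 to 2278 in 93-11. Mean CHH sites went only from 680 to 636 and from 717 to 613. Between the same groups of windows the mean CHH level went from 42.6% to 36.3% in Nipponbare and from 42.9% to 38.9% in 93-11, while the mean CG level went from 90.8% to 95.4% and from 90.1% to 95.4%. On chromosome 1 the window with the most CG sites lay at 16.4 to 16.5 Mb in Nipponbare, with 2917 CG and 721 CHH sites. In 93-11 it lay at 21.1 to 21.2 Mb, with 3454 CG and 903 CHH sites.

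**Figure D3:**
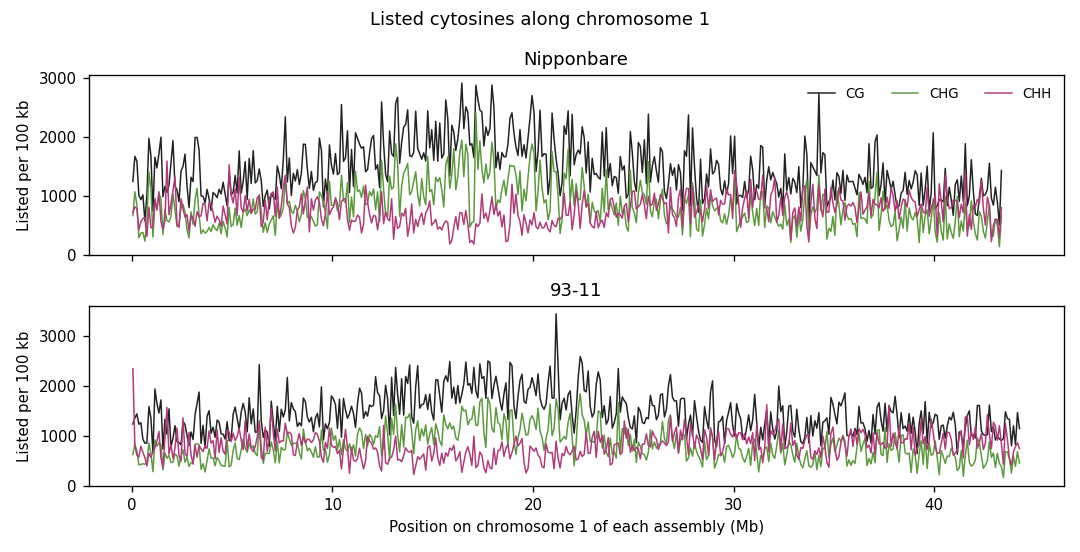
Listed cytosines per 100 kb (vertical axis) along chromosome 1 (horizontal axis, Mb of each cultivar's own assembly), 1 line per context and 1 panel per cultivar. CG and CHG rise together toward the middle of the chromosome where CHH is low, and the first window of 93-11 holds 2354 CHH sites.

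Some CG-rich sequence carried no other listed methylation, a pattern known in plants from the bodies of expressed genes. Of 188587 bins of 1 kb with at least 10 CG sites in Nipponbare, 25538 (13.5%) had neither CHG nor CHH sites, and their CG level was 90.9%. In 93-11 these were 27030 of 198679 bins (13.6%), with a CG level of 90.8%. Bins with at least 3 CHG sites as well made up 81.4% in Nipponbare and 81.0% in 93-11, with CG levels of 95.3% and 95.03%. Whether the CG-only bins lay in genes was not analysed here.

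CHG methylation depended on the base between C and G. Sites placed as CAG or CTG had a level of 81.4% in Nipponbare and 77.7% in 93-11, and CCG sites had 57.7% and 57.8%. The difference was 23.8 points in Nipponbare (22.3 to 25.2 over the 12 chromosomes) and 19.9 points in 93-11 (18.1 to 21.6). Sites of the first kind were recognised by a listed partner on the other strand, which favours methylated sites. The remaining CHG sites, not placed in either class, had 77.97% and 75.6%. With at least 20 reads per site the difference in 93-11 was 14.0 points.

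Opposite strands were compared where both cytosines were listed, which leaves out pairs with an unmethylated member. Across 1010310 CG pairs in Nipponbare the mean absolute difference between strands was 4.62 points, and across 421150 CHG pairs it was 8.25 points. In 93-11 the values were 4.73 points over 1102177 CG pairs and 8.78 points over 445984 CHG pairs. Much of this is counting error. The SD of the difference was 6.95 points for CG and 11.2 for CHG in Nipponbare, and counting alone would give 5.59 and 8.85. In 93-11 the SDs were 7.18 and 11.8 points, against 5.71 and 9.26 from counting alone. Ranked levels of the strands correlated with rho = 0.389 for CG and 0.751 for CHG in Nipponbare, and with 0.439 and 0.788 in 93-11, across pairs that are not independent. Most listed CG sites are near full methylation, with a median level of 97% in both lists, which keeps their differences small for any pair. Differences of at least 50 points were found at 146 CG and 203 CHG pairs in Nipponbare and 197 and 222 in 93-11. Only 32.6% of listed CG sites in Nipponbare and 36.2% in 93-11 had their partner listed. A partner under 10 reads is absent as well as an unmethylated one, so these shares do not measure methylation of 1 strand alone.

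Where the same sequence was matched in both cultivars, the CHG and CHH differences had the same direction and the CG difference the opposite one. Matched stretches covered 18.1 Mb of Nipponbare. At 354448 CHG sites listed in both, the mean level was 75.5% in Nipponbare and 74.0% in 93-11, a difference of 1.499 points. At 171020 CHH sites the means were 50.1% and 51.9%, a difference of -1.80 points. At 809717 CG sites they were 95.5% and 95.7%, a difference of -0.173 points. Each of these directions held on 12 of 12 chromosomes. Of the sites listed in either cultivar within these stretches, 76.2% of CG, 65.0% of CHG and 42.8% of CHH sites were listed in both. With at least 20 reads, a setting chosen after seeing the data, the CHG share was 36.4% and the CHH share 33.2%. A cytosine under the read minimum in 1 list counts as not listed there, so these shares depend on depth as well as on methylation. Levels at sites listed in both correlated with r = 0.521 for CG, 0.817 for CHG and 0.829 for CHH across sites, which are not independent.

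Level differences of at least 50 points were counted only at matched sites listed in both cultivars, so a site methylated in 1 cultivar and absent from the other list does not enter. A difference of at least 50 points occurred at 0.649% of CHG sites, 1464 higher in Nipponbare and 837 higher in 93-11. It occurred at 0.312% of CHH sites, 227 higher in Nipponbare and 306 in 93-11, and at 0.235% of CG sites, 1017 and 887.

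A small number of matched stretches had many listed CHG sites in 1 cultivar and 0 in the other. A site can be absent from a list through coverage under 10 reads as well as through low methylation. Of 53410 stretches, 14279 had at least 10 CHG sites in both lists. There were 20 with at least 10 CHG sites in Nipponbare and 0 in 93-11, and 43 of the opposite kind. Some of these lay close together, so the counts are of stretches and not of separate places. Examples are 804227 to 805103 and 805888 to 806135 on chromosome 1 of Nipponbare. On chromosome 1 of 93-11, 9145608 to 9147790 and 9148001 to 9148802 lay close together. The stretch with the most CHG sites in Nipponbare alone lay on chromosome 1 at 804227 to 805103 of its assembly, with 42 CHG sites at 74.2%. It had 27 CG sites at 94.4% in Nipponbare and 22 at 95.2% in 93-11, with mean CG coverages of 17.0 and 15.3 reads. The stretch with the most in 93-11 alone lay on chromosome 1 at 9145608 to 9147790 of the 93-11 assembly, with 85 CHG sites at 68.3%. Its CG level was 94.3% in 93-11 and 88.1% in Nipponbare, at 19.4 and 22.8 reads. The next one, with 61 CHG sites at 79.1%, lay on chromosome 11 at 22518289 to 22519121. These stretches were chosen after their values were seen. No gene annotation was used for them.

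Chromosomes 2 and 7 of the lists do not hold the same sequence. The last listed site of chromosome 2 was at 36.0 Mb in Nipponbare and 48.4 Mb in 93-11, and that of chromosome 7 at 29.5 Mb and 20.3 Mb. Nipponbare chromosome 7 from 15.8 to 26.0 Mb matched 93-11 chromosome 2 from 31.9 to 41.6 Mb in the opposite direction, through 4936 matches. Other pairs of different chromosomes had a median of 81 inverted matches and at most 222. As numbered, 93-11 had 1.31 times the listed cytosines of Nipponbare on chromosome 2 and 0.670 times on chromosome 7. With the 288663 cytosines of the block moved to chromosome 7 these ratios were 1.052 and 0.956. A further inverted block lay on chromosome 6, from 13.2 to 17.7 Mb in Nipponbare and from 13.1 to 18.8 Mb in 93-11, with 3820 matches. It was less uniform. Inside it 528 matches of the 93-11 chromosome had the same direction, or 92.5 per Mb. Inside the block on 93-11 chromosome 2 there were 14, or 1.43 per Mb.

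**Figure D4:**
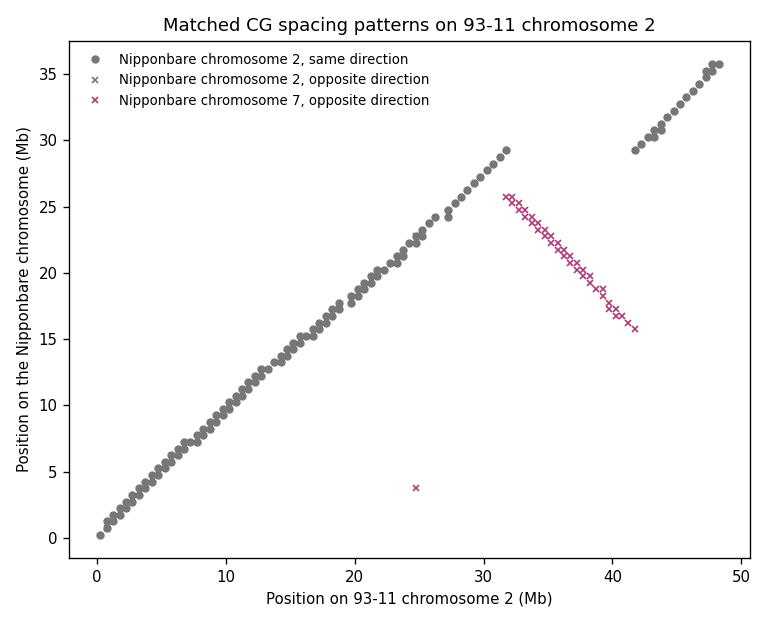
Squares of 0.5 Mb with at least 20 matched CG spacing patterns between 93-11 chromosome 2 (horizontal axis, Mb) and Nipponbare chromosomes 2 and 7 (vertical axis, Mb), circles for the same and crosses for the opposite direction. Between 31.9 and 41.6 Mb the chromosome matches Nipponbare chromosome 7 in the opposite direction.

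Many chromosome ends carried dense CHH methylation in steps of 7 bp, on the plus strand at the low end and the minus strand at the high end. The plant telomere repeat CCCTAAA has the same length and a run of 3 cytosines. Such arrays were found at 15 of 24 ends in Nipponbare, with 3756 sites, and at 13 of 24 ends in 93-11, with 10601 sites. Within the triplets the last cytosine was the most methylated at each of these ends. Averaged over ends, the 3 cytosines had levels of 73.0%, 74.96% and 93.3% in Nipponbare and 64.3%, 66.9% and 92.3% in 93-11. The last exceeded the mean of the first 2 by 19.3 ± 11.2 points (SD over 15 ends) and 26.8 ± 4.52 points (SD over 13 ends). The lowest excess was 5.05 points, on chromosome 11 of Nipponbare. Median coverage in the arrays was 16 and 18 reads.

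**Figure D5:**
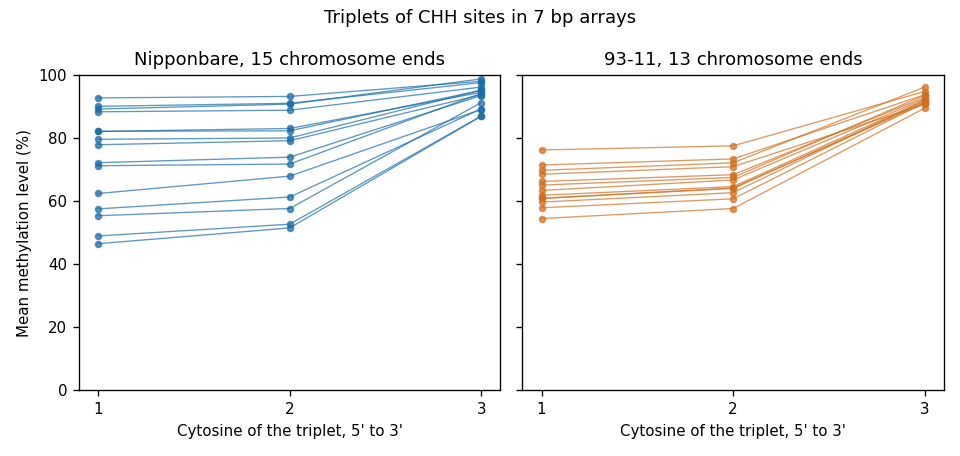
Mean methylation level (vertical axis, percent) of each cytosine of the triplets (horizontal axis, read 5' to 3'), 1 line per chromosome end with an array. In all 15 Nipponbare and 13 93-11 ends the third cytosine is highest.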

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

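Sequences other than chromosomes 1 to 12 were left out of the comparisons and carried listed methylation. There were 107759 such cytosines on 96 sequences in Nipponbare and 152582 on 114 sequences in 93-11. Their read-weighted CG levels, 93.4% and 94.3%, were near those of the chromosomes, while their read-weighted CHH levels were 11.9% and 22.5%. Deep sites weigh more in such levels, which need not be those of a typical site. A sequence numbered 14 in the 93-11 list held 1 listed cytosine, a CHH site at position 296010 with 149 reads and a level of 2%.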

How the results depend on the processing

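The settings with at least 20 reads, ranges of coverage, rounded counts or equal coverage, and those for the CHG classes, matched sites, chromosome block and arrays, were chosen after seeing the data. Minimums of 1 and 10 reads removed no cytosine, so they say nothing about stability. No paired analysis was possible because each list combines both replicates of a cultivar, and for the same reason no fit without a replicate was made. Alternatives on genes, flanks and reference cytosines were not run, as no annotation or genome of these builds was used. Depth limits the lists at 10 reads, and the small counting errors make most values below lie outside the 95% interval of the main value.

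The level differences kept their direction in these settings except within ranges of coverage, and at matched sites the CG difference had the opposite sign, as the report gives. Nipponbare minus 93-11, in points for CG, CHG and CHH, was 0.221, 1.27 and -1.40 with the mean level, 0.456, 1.38 and -2.09 for the share of sites with a level of at least 50%, 0.388, 1.48 and -1.39 without the highest coverages, 0.403, 1.54 and -1.48 on the plus strand, 0.465, 1.61 and -1.21 on the minus strand, and 0.408, 1.497 and -1.67 with all sequences. With at least 20 reads it was 0.731, 2.07 and -1.88, and at equal coverage 0.0482, 1.11 and -1.85. At 10 to 14 reads alone it was -0.293, 0.595 and -1.17, with CG reversed, at 15 to 19 reads 0.218 for CG and -1.28 for CHH, at 20 to 29 reads 0.517, 1.78 and -2.38, and at 30 or more 0.173, -0.368 and -6.64, with CHG reversed. With rounded counts CG and CHG gave 0.426 and 1.54. The cause was not tested, and equal coverage changes the coverage range and the averaging together with depth. The number of chromosomes with the higher level in Nipponbare was the same at each coverage minimum run, 20 reads included.

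With at least 20 reads, 1782985 CG, 964449 CHG and 798898 CHH sites stayed in Nipponbare and 1404618, 728303 and 763144 in 93-11, fewer by construction. At a level of at least 50%, 836576 CHH sites stayed in Nipponbare and 937393 in 93-11.

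The CAG or CTG excess over CCG in Nipponbare and 93-11 was 21.3 and 14.0 points with at least 20 reads, 23.8 and 19.9 on the plus strand, and 21.4 and 18.5 with all other CHG sites set against CCG; the cause was not tested. Matched CG, CHG and CHH differences were -0.145, 1.59 and -1.60 with 6 distances, -0.198, 1.44 and -1.98 with 10, and -0.189, 1.06 and -2.08 with at least 20 reads. The CHG and CHH shares listed in both were 62.9% and 39.9%, 66.4% and 44.9%, and 36.4% and 33.2% in these settings. An offset of 5 kb left these values within their intervals. The shares listed in both depend on depth as well as on methylation. Array sizes of at least 12 or 48 sites left the excess of the third cytosine within its spread over ends, and the number of ends within 1.5 times.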

Other observations

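The tests of the arrays at chromosome ends and of the chromosome 7 block, and the comparisons of mean coverage and of offsets and the thinning on chromosome 5, were chosen only after the results were seen. The other tests of chromosome 5 were written down beforehand.

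Partner listing went with coverage differently in the 2 cultivars. In Nipponbare 42.0% of CG sites with 10 reads had their partner on the other strand listed, against 24.6% of those with 20 to 24 reads and 86.0% of those with 50 to 99. In 93-11 the shares were 35.1%, 34.4% and 89.9%. Sites with at least 30 reads also had higher CHH levels, 51.5% in Nipponbare and 58.2% in 93-11, against 38.9% and 41.3% at 20 to 29 reads. Apart from the chromosome ends, 93-11 had 2 arrays in 7 bp steps inside chromosomes, on the minus strand of chromosome 3 at 25459144 to 25459232 and on the plus strand of chromosome 4 at 28466263 to 28466362.

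The arrays of CHH sites in 7 bp steps may be methylated telomeric repeats, since at least 99.4% of their sites lay within 30 kb of an end on the strand where the C-rich telomere repeat would lie. Failure of bisulfite conversion that is equal at each cytosine would give equal levels within a triplet, and the third cytosine exceeded the first 2 by 22.8 points over all ends. Many copies collapsed onto 1 place would raise coverage if reads that fit several places were kept. Median coverage was at most 1.06 times that of all CHH sites. The lists do not show whether such reads were kept, so collapsed copies are not excluded. Conversion that fails more at the third cytosine than at the others stays open, as the lists hold no unmethylated control. No biological explanation between the cultivars was tested.

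On chromosome 5 of Nipponbare from 8 to 14 Mb, 36.3% of CG dinucleotides lay in stretches matched to 93-11, against 16.7% in the rest of the chromosome; 7 of 361 other windows of 1 Mb reached the lowest window of the region. Deeper coverage is argued against by mean coverage, 1.005 times that of the rest in Nipponbare and 0.981 times in 93-11. The share of CG sites with a listed partner was at most 0.829 times that of the rest. This share cannot test depth, as in neither list was it higher at 20 to 24 reads than at 10 reads. Reads of 93-11 mapped to Nipponbare sequence stay open, since sites that lose reads leave the list. Thinning 93-11 sites of the rest to 80% of their depth lowered median coverage to 0.875 times and mean coverage to 0.848 times. In the region the 93-11 ratios to the rest were 1 for the median and 0.981 for the mean. These ratios argue against a loss as large as the thinning, but not against a smaller one. Dense CG sites are not excluded, since 1 of 125 equally dense windows of other chromosomes reached the lowest window of the region. The median share over the 125 was 11.3%, against 31.5% in the lowest window of the region, so high density by itself did not go with shares as high as the region's. Near-identical sequence of both cultivars stays open, because the shares of sites listed in both, 1.04 times the rest for CHG and 0.879 times for CHH, were taken only inside stretches matched by identical spacing and cannot test it. Fewer insertions and deletions between the cultivars may contribute, since neighbouring matches 500 to 5000 bp apart kept the same offset in 76.5% of 1087 cases (73.9 to 79.0) against 32.4% of 1388 in the rest, at least 1.69 times as often at each of 3 gap lengths.

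The block of Nipponbare chromosome 7 on chromosome 2 of 93-11 held 4936 inverted matches. Repeats shared by different chromosomes are argued against by the other pairs of different chromosomes, with a median of 81 and at most 222 inverted matches; shuffled distances, which remove such repeats, gave 0 for this pair. The block spans 9.76 Mb of the 93-11 assembly. A rearranged chromosome in the plants and a wrong join in the assembly cannot be told apart, because both put the same cytosines on the same sequence.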
